A study of Mus musculus with 16 samples.

How the data were processed

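RNA from mouse primary calvarial osteoblasts was measured on 16 Illumina single-colour bead arrays, 4 for each of 4 transfections. The cells came from the skull bones of C57BL/6J mice aged 3 to 9 days, of mixed sex per the labels, and RNA was taken 48 hours after transfection with a scrambled siRNA (SC) or with 1 of 3 siRNAs to Bicc1 (BICC1_1, BICC1_2 and BICC1_3). Groups and replicate numbers were taken from the sample titles. The labels do not say whether replicates were separate cultures or separate pools of mice, so every p-value measures only the spread between these arrays, which may be technical.

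The deposited table of probe intensities holds a mean bead intensity on a linear scale for each probe and array, not normalised between arrays, per the file headers. GenomeStudio is named in the submitters' processing notes. Beside each intensity the deposited table holds a detection score. It is headed as a p-value per the file headers, but it lies near 1 for bright probes and near 0 for dim ones, so the detection p was taken as 1 minus the score. The authors also deposited a table of log2 values with the same quantiles on every array. Within each array its values rank the probes exactly as the intensity does (Spearman correlation 1). They rise by 0.989 to 1.08 per unit of log2 intensity above an intensity of 1000 and by 0.276 to 0.384 below 100. Its transform and normalisation are not given in the sources used here, so it served only as an alternative.

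Intensities were background-corrected and normalised with neqc of limma 3.58.1 in R 4.3.3, which fits a normal-exponential model to the detection p-values, adds an offset of 16, quantile-normalises and takes log2. Of 25697 probes, 23978 carried 1 gene symbol in the platform annotation, 0 carried several and 1719 carried none. The Entrez identifiers of 23962 named probes were found in a RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols and was used only for names and for the genomic span of genes. A probe was kept when its detection p was under 0.05 on at least 4 arrays, which left 12802 probes. The probe with the highest mean over all 16 arrays stood for each gene, for 2332 genes chosen among more than 1 kept probe. This left 9560 genes or unnamed probes for testing, 8832 of them with a symbol and 728 without. No probe of Pkd2 was paired with it in the annotation used, so Pkd2 is not analysed here.

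The depth behind each array was 84.8 to 111.3 in median intensity and 11990 to 12863 probes detected. The number of arrays limits the precision. With 4 arrays a group, the median standard error of a log2 fold change was 0.108 for 1 siRNA against SC and 0.0878 for the mean of the 3 siRNAs. No pair of arrays held identical values.

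A single linear model over the 4 groups was fitted with limma (lmFit and eBayes, 12 residual and 3.962 prior degrees of freedom), so all groups shared 1 estimate of each gene's spread. Each siRNA was compared with SC, the mean of the 3 siRNAs with SC, and each siRNA with each other siRNA. Adjusted p stands for limma's moderated test after Benjamini-Hochberg adjustment over all 9560 tested, with a threshold of 0.05. Intervals are 95% intervals from the same fit. The fit was tested on simulated data in which 67 genes changed by 0.5 log2, 67 by 1 log2 and 66 by 2 log2 at once. The noise was independent between genes, with no array that stood apart. Against SC the fit called 65.7% of the genes changed by 0.5 log2 and 92.5% of those changed by 1 log2 in the BICC1_1 comparison. It called 59.7% and 94.0% in the BICC1_2 comparison, 61.2% and 94.0% in the BICC1_3 comparison, and 82.1% and 98.5% for the mean of the 3 siRNAs. Far fewer genes passed against SC in the real data, which makes the adjusted threshold stricter, so these shares may be too high for them.

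The gene lists were tested with camera at a preset correlation of 0.01 between genes, Benjamini-Hochberg adjusted over 20 lists with at least 5 tested members, and again with camera's estimated correlation and with fry. The lists covered polycystin and Bicc1 partners, osteoblast and mineralisation genes, collagen and bone matrix, BMP and TGF-beta targets, Wnt/beta-catenin targets, calcium and calcineurin/NFAT signalling, proliferation, p53 targets, the interferon response, inflammatory cytokines and NF-kB targets, endoplasmic reticulum stress and ATF4 targets, cholesterol synthesis, hypoxia and glycolysis, and actin, smooth muscle and YAP/SRF targets. They also covered markers of adipocytes, chondrocytes, macrophages, osteoclasts, endothelial cells and skeletal muscle. Members were also adjusted over the list alone. Fold changes of different siRNAs were correlated across genes. Because the comparisons share the SC arrays, each correlation stands beside 100 simulated sets of unchanged groups with simulated shared controls. The simulated noise was independent between genes. Each correlation also stands beside the value with the SC arrays split 2 and 2 in all 6 ways.

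Groups, comparisons, tests, lists, the named-gene rule and all alternatives except 2 were fixed before the data were examined. The rule named Bicc1, Pkd1 and Pkd2. It named the 12 highest and 12 lowest genes changed the same way by all 3 siRNAs, the 5 highest and 5 lowest past the test for each siRNA, and the 3 highest and 3 lowest past the test for each pair of siRNAs. For each list it named up to 4 members past the test, or the 2 with the largest fold change where 0 passed. Unnamed probes and clone-like symbols were counted but passed over. The alternatives were no background correction, median scaling, the authors' value table, other detection filters, every probe tested, the replicate number as a block, separate fits for each pair of groups, array quality weights, each array left out in turn, stricter thresholds and other list tests. Leaving out 3 or 2 arrays that stood apart was added after seeing the data.

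Replicate numbers were checked by correlating the deviations of arrays from their group means. Between BICC1_1 and BICC1_2 all 4 same-numbered pairs correlated at over 0.1 (0.182, 0.257, 0.609 and 0.219, against -0.423 to 0.296 for other numbers), so for this comparison values with the replicate number as a block are given where they change a call or count. The pair at 0.609 joins arrays that stood apart. In the other 5 pairs of groups at least 2 of 4 same-numbered correlations were 0.1 or less. The labels do not say what a number shares.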

Results

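Gene expression was measured in primary mouse osteoblasts, the bone-forming cells of the skull, after siRNA knockdown of Bicc1, which encodes an RNA-binding protein. The 16 arrays form 4 groups of 4. The control group received a scrambled siRNA (SC), and the others received BICC1_1, BICC1_2 or BICC1_3, siRNAs meant to lower the same transcript. An effect of losing Bicc1 would be shared by siRNAs that lower it to a similar degree, while an effect of a single siRNA's sequence would not. The arrays detected 11990 to 12863 probes each, and pairs of arrays correlated at 0.973 to 0.997.

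Bicc1, read by 1 probe, was lower in 2 of the 3 siRNA groups. Its log2 intensity was 10.59, 10.66, 10.59 and 10.38 on the SC arrays (mean 10.55 ± 0.12 SD, n = 4). With BICC1_1 it was 9.51, 9.81, 9.88 and 9.42 (9.66 ± 0.22), and with BICC1_2 it was 8.87, 9.04, 9.27 and 8.69 (8.97 ± 0.25). The arrays labelled BICC1_3 gave 10.70, 10.39, 10.39 and 10.33 (10.45 ± 0.17), a range that overlaps SC. Bicc1 therefore stood at 53.7% of control with BICC1_1 (95% interval 44.3 to 65.0, adjusted p = 0.0345) and at 33.3% with BICC1_2 (27.5 to 40.3, adjusted p = 7.98e-06). In the arrays labelled BICC1_3 it stood at 93.3% of control (77.1 to 113, adjusted p = 0.776). The highest value there (10.70) came from replicate 1, which stood apart as described below. Over 27 alternatives the log2 difference from SC lay at -0.182 to -0.0592, none past the test. The transcript thus goes against the label of that group, and any direction drawn from it is a direction in arrays labelled BICC1_3 in which a loss of Bicc1 mRNA was not detected. The fall with BICC1_2 passed the test under all 27 alternatives. The fall with BICC1_1 kept its size (log2 -0.97 to -0.78 over 27 alternatives) but missed the threshold in 12 of them, with adjusted p from 0.000437 to 0.224. These were median scaling (0.224), separate fits (0.145) and leaving out SC replicate 1, 2 or 3, BICC1_1 replicate 1, 2 or 4, BICC1_2 replicate 1 or 2, or replicate 2 or 3 of the arrays labelled BICC1_3 (0.0507 to 0.169). Pkd1, which encodes polycystin-1, differed from SC by 0.06, 0.13 and 0.08 log2 with BICC1_1, BICC1_2 and the arrays labelled BICC1_3, and none of these passed the test (adjusted p = 0.97, 1.00 and 0.769).

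**Figure D1:**
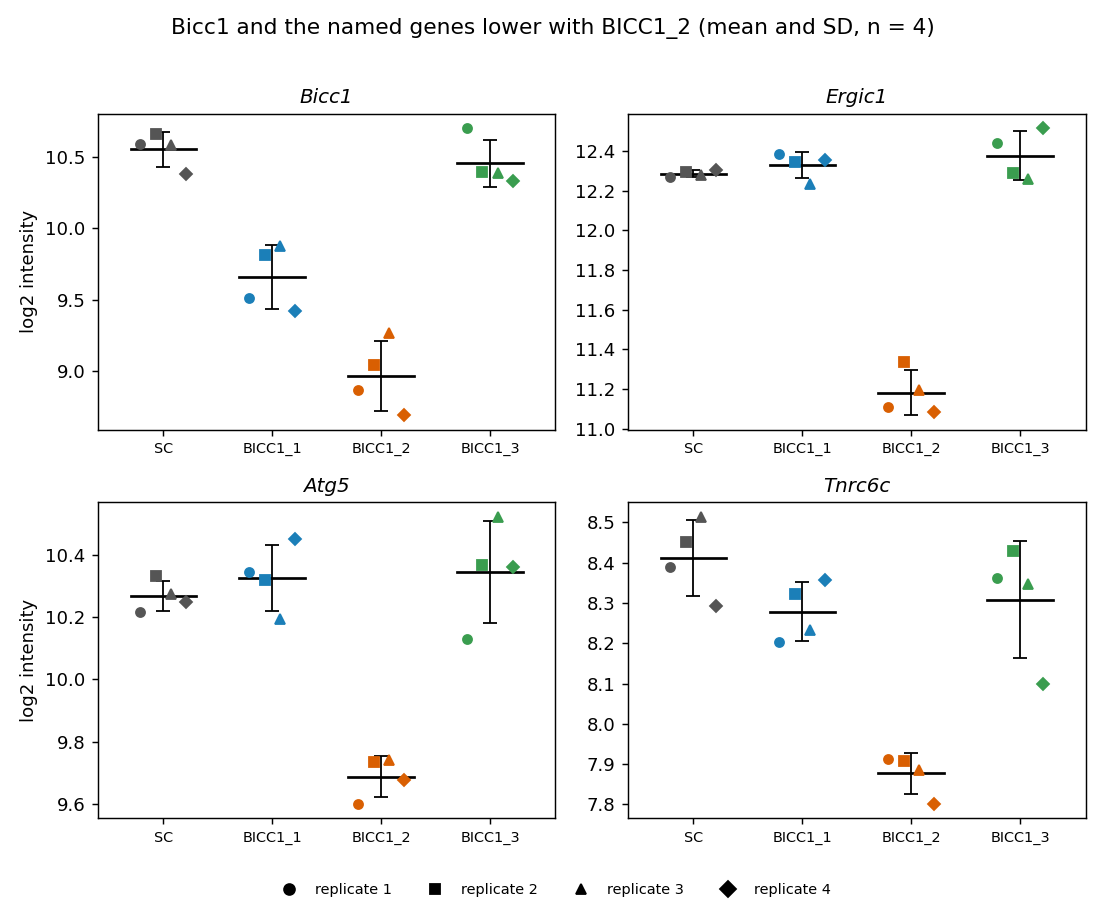
Log2 intensity of Bicc1 and of the other named genes that passed the test with BICC1_2 on each array, with group means and SD (n = 4). Bicc1 lies at 9.66 with BICC1_1 and 8.97 with BICC1_2 against 10.55 in SC, while Ergic1, Atg5 and Tnrc6c pass the test against SC with BICC1_2 alone.

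Ribosomal and mitochondrial genes set 2 arrays apart from the rest, and a further array to a smaller degree. Against the mean of the other 13 arrays, the median of 51 cytoplasmic ribosomal protein genes lay at -0.81 log2 on replicate 1 of the arrays labelled BICC1_3 and at -0.46 on BICC1_1 replicate 3, where the other 13 arrays spanned -0.05 to 0.03. The median of 39 NADH dehydrogenase genes, which encode subunits of respiratory complex I, lay at -1.39 and -0.59, against -0.04 to 0.04. BICC1_2 replicate 3 lay at -0.10 and -0.18. On the first 2 arrays both families were lower under every scaling tried, and on BICC1_2 replicate 3 the NADH dehydrogenase median (-0.10) fell inside the range of the other arrays with median scaling. Below, values without these 3 arrays are given where they change a call or move a called value by over 1.5 times. This comparison was chosen after the data were seen.

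**Figure D2:**
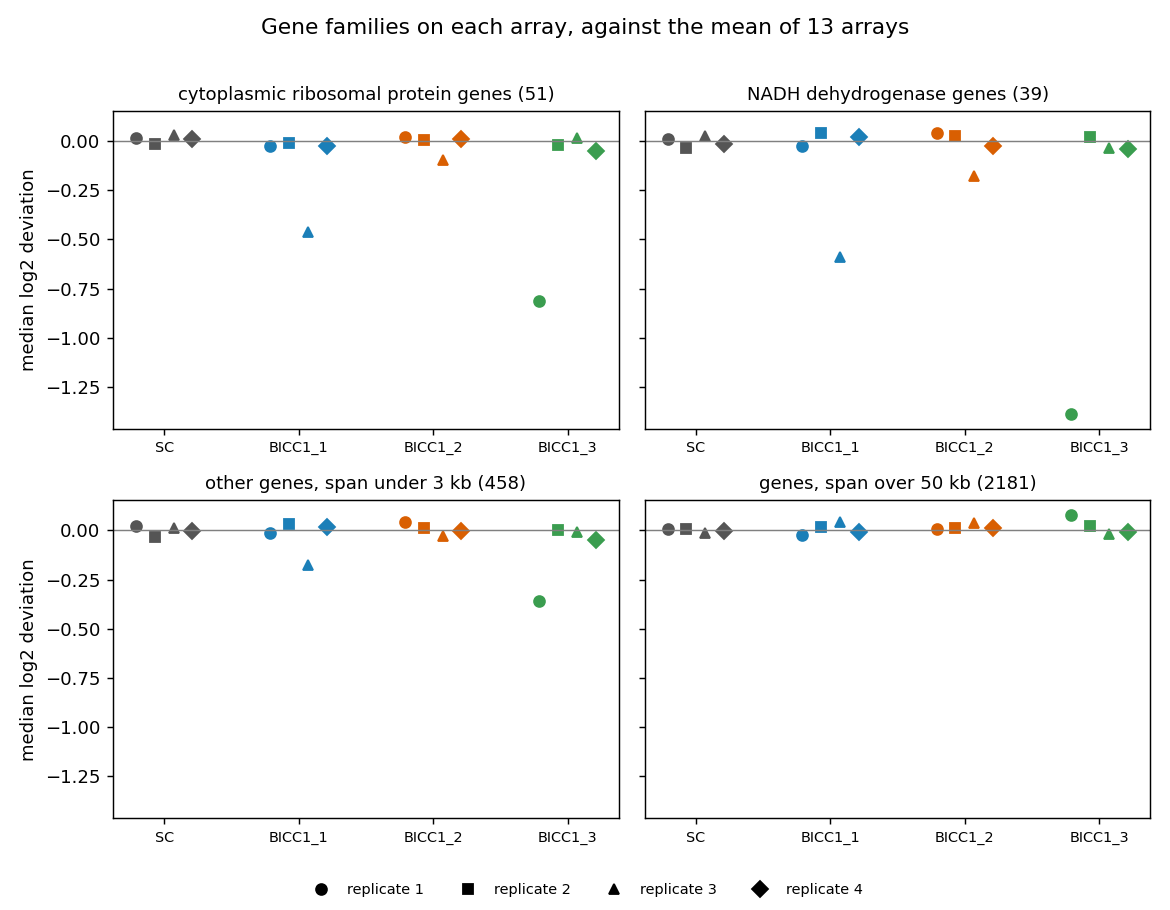
Median log2 deviation of 4 sets of genes on each array from the mean of the 13 arrays that did not stand apart, by group, with the number of genes in each set. Replicate 1 of the arrays labelled BICC1_3 and BICC1_1 replicate 3 lie below the others for ribosomal protein genes (-0.81 and -0.46) and NADH dehydrogenase genes (-1.39 and -0.59).

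The comparison of BICC1_1 with SC asked what this siRNA changed. Bicc1 fell by 0.90 (log2, SE 0.13), as given above. Fam177a was the other gene that fell, by 0.50 log2 (SE 0.08, adjusted p = 0.0440), from 11.40 ± 0.04 in SC to 10.90 ± 0.14 (SD, n = 4), lower on 4 of 4 arrays than on any SC array. A further Fam177a probe gave -0.19. Mrgprf, an orphan G protein-coupled receptor gene, lay at -0.56 log2 and the neutrophil chemokine gene Cxcl1 at -0.96, neither past the test. In all, 2 of 9560 genes passed limma's test, 0 higher and 2 lower, and 589 had an unadjusted p under 0.05 where 478 are expected by chance. Fam177a lost its call in 18 of 27 alternatives (adjusted p 0.00823 to 0.528), among them the fit without the 3 arrays. The count was 0 with median scaling, with separate fits, and without SC replicate 1, 2 or 3, BICC1_1 replicate 1 or 2, BICC1_2 replicate 1 or 2, or replicate 2 or 3 of the arrays labelled BICC1_3, 1 without BICC1_1 replicate 3 or 4 or BICC1_2 replicate 3 or 4, 5 without SC replicate 4, and 30 with array quality weights (13 higher, 17 lower). Without the 3 arrays that stood apart it was 3, 2 higher and 1 lower.

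The comparison of BICC1_2 with SC gave the clearest changes besides Bicc1 itself. Ergic1, whose protein cycles between the endoplasmic reticulum and the Golgi, fell by 1.10 log2 (SE 0.07, adjusted p = 9.27e-07), to 46.5% of SC, and its adjusted p was lower than that of Bicc1. Atg5, needed to form autophagosomes, fell by 0.58 (SE 0.08, adjusted p = 0.00797), with a further probe at -0.60. Tnrc6c, a partner of Argonaute in silencing by microRNAs, fell by 0.54 (SE 0.08, adjusted p = 0.00899). Each of these genes was lower on 4 of 4 BICC1_2 arrays than on any SC array. Ergic1, Atg5 and Tnrc6c stood at 0.04, 0.06 and -0.13 log2 with BICC1_1, and at 0.09, 0.08 and -0.10 in the arrays labelled BICC1_3, none past the test. In all, 5 of 9560 passed the test, 0 higher and 5 lower, Bicc1 and an unnamed probe among them, and 501 had an unadjusted p under 0.05 where 478 are expected by chance. Ergic1 passed in all 27 alternatives (-1.16 to -1.07), while Atg5 missed the threshold with median scaling (adjusted p = 0.344) and without SC replicate 2 (0.0587), in a range of 2.17e-05 to 0.344 over its alternatives, and Tnrc6c with median scaling (0.284) and without SC replicate 2 (0.0605) or 3 (0.0524), in a range of 0.00128 to 0.284. The count was 2 with median scaling or without SC replicate 2, 9 without replicate 1 of the arrays labelled BICC1_3, 11 without the 3 arrays that stood apart (2 higher, 9 lower) and 60 with array quality weights (27 higher, 33 lower). With the authors' table, which is compressed at low intensity, Tnrc6c lay at -0.31 and still passed.

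In the arrays labelled BICC1_3, Hsd3b2 was the gene that passed the test against SC. It encodes an enzyme of steroid hormone synthesis, and its probe rose by 0.53 log2 (SE 0.07, adjusted p = 0.0128), from 10.64 ± 0.11 in SC to 11.17 ± 0.03 (SD, n = 4), higher on 4 of 4 arrays than on any SC array. The other Hsd3b2 probes were not detected, with mean log2 intensities of 4.55 to 4.90, so the rise rests on a single probe. Bmp4, a bone morphogenetic protein gene, lay at -0.54 and Sostdc1, whose product antagonises BMP and Wnt signals, at -0.48, neither past the test. In all, 1 of 9560 genes passed, 1 higher and 0 lower, and 883 had an unadjusted p under 0.05 where 478 are expected. Hsd3b2 missed the threshold in 7 of 27 alternatives (adjusted p 0.00136 to 0.21), and the count was 0 without the 3 arrays that stood apart, with median scaling, with separate fits and without SC replicate 1, 2 or 4 or replicate 4 of the group itself. It was 12 without replicate 2 of the group and 14 with array quality weights (10 higher, 4 lower).

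Across the 3 siRNAs, Bicc1 was the gene that changed. The mean of the 3 siRNAs against SC lowered Bicc1 by 0.86 log2 (SE 0.11, adjusted p = 0.00452), although the arrays labelled BICC1_3 added little to it. Bicc1 was also the gene that both BICC1_1 and BICC1_2 lowered past the test, where 0.00105 genes are expected from independent lists. The lists share their controls, and 100 simulated sets of unchanged groups with shared controls gave at most 0. Genes of unchanged groups rarely pass an adjusted threshold, so this 0 was nearly fixed in advance. Bicc1 is the target of both siRNAs, so neither number tells of an overlap beyond the target. The number of genes changed the same way by all 3 siRNAs was 0 by limma, and it was 0 under all 29 alternatives. Bicc1 itself did not meet this rule, as no fall was detected in the arrays labelled BICC1_3. The count therefore says little about an effect of losing Bicc1. Stricter thresholds could only keep a count of 0, and BICC1_1 and BICC1_2 were not tested together without the third group. At an unadjusted p under 0.05 in each comparison, 53 genes went the same way in all 3, 36 higher and 17 lower, while unchanged groups simulated against the same controls gave a median of 42 (30 to 61 over 100 sets). With median scaling there were 29, 27 higher and 2 lower. In the mean comparison 1 of 9560 genes passed, 640 had an unadjusted p under 0.05, and the count was 0 without SC replicate 2 and 26 with array quality weights (19 higher, 7 lower).

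**Figure D3:**
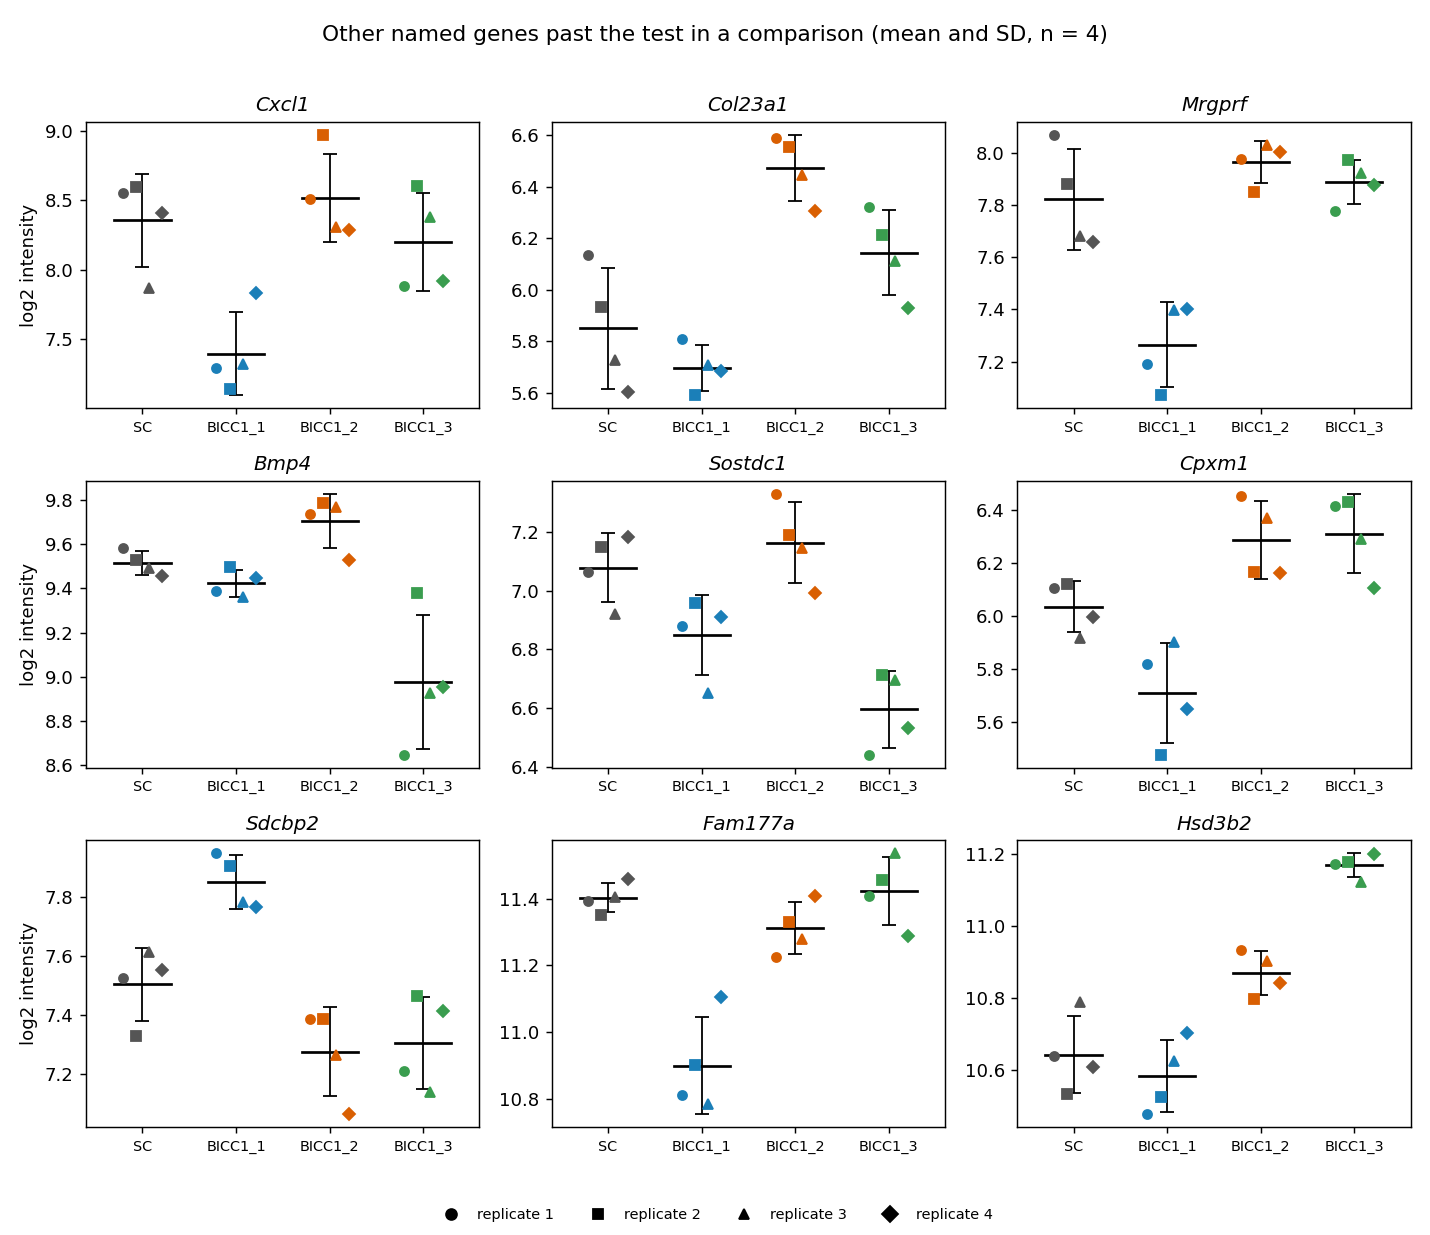
Log2 intensity on each array of the other named genes that passed the test in a comparison with SC or between siRNAs, with group means and SD (n = 4). Fam177a, Mrgprf, Cxcl1 and Cpxm1 lie lower with BICC1_1, while Bmp4 and Sostdc1 lie lower and Hsd3b2 higher in the arrays labelled BICC1_3.

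Proliferation genes and p53 targets were the 2 of 20 lists that passed camera's preset test in the mean of the 3 siRNAs against SC. Targets of p53 lay higher, 19 of 22 tested members above 0 with a mean of 0.07 log2 (camera adjusted p = 0.00233). The adjusted p was 0.446 with an estimated correlation. Trp53inp1, a stress-induced p53 target, lay at 0.22, and Tnfrsf10b, a death receptor gene, went against its list at -0.41. Tnfrsf10b has 4 kept probes, of which the brightest is given, and its value ranged from -0.458 to -0.0179 over 26 alternatives. Proliferation genes lay lower, 24 of 31 below 0 with a mean of -0.07 log2 (camera adjusted p = 0.00735). Here too the adjusted p was 0.446 with an estimated correlation. Ube2c and Tpx2, both used in mitosis, lay at -0.22 and -0.18, with Ube2c not detected on 3 of 16 arrays. In both lists 0 members passed the test over all genes and 0 passed when adjusted over the list alone. The p53 mean was 0.05 (adjusted p = 0.0187) without the 3 arrays that stood apart, and the proliferation call ended without replicate 2 of the arrays labelled BICC1_3 (adjusted p = 0.0704), and its mean was -0.04 (adjusted p = 0.0210) with median scaling. No list passed with an estimated correlation (lowest adjusted p = 0.446) or by fry (lowest 0.236).

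No list of bone or cartilage genes passed the test in the mean comparison. Of 18 osteoblast and mineralisation genes 12 lay below 0 (adjusted p = 0.706), with the mineralisation inhibitor gene Mgp at -0.21 and the cadherin gene Cdh11 at 0.19. Of 30 collagen and bone matrix genes 17 lay above 0 (adjusted p = 0.706), with Thbs1 at 0.38 and the lysyl oxidase gene Loxl4 at 0.28. Of 6 chondrocyte markers 4 lay below 0 (adjusted p = 0.760). The cartilage transcription factor gene Sox9 (0.34) and its collagen target Col2a1 (-0.33) both passed when adjusted over the list alone (0.00607 each), while neither passed over all genes. Of 9 osteoclast markers 5 lay below 0 (adjusted p = 0.760), with the receptor gene Tnfrsf11a at 0.31 and the gelatinase gene Mmp9 at -0.36, which passed when adjusted over the list alone (0.0418). The osteoclast mean was slightly negative while camera's direction was up. The mean comparison averages siRNAs that went different ways, and includes the arrays labelled BICC1_3, in which no fall of Bicc1 was detected. The osteoblast mean was -0.08 with BICC1_1 and 0.03 with BICC1_2, and the collagen mean -0.04 and 0.05, none past camera's test. These results therefore do not exclude a response of bone genes to 1 siRNA.

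Signalling lists did not pass either. Of 10 Wnt/beta-catenin targets 6 lay above 0 (adjusted p = 0.621). Nkd2, an antagonist of Wnt signalling, lay at -0.31 and the cell adhesion gene Nrcam at 0.25, and both passed when adjusted over the list alone (0.00749 and 0.0120). Of 16 BMP and TGF-beta targets 9 lay above 0 (adjusted p = 0.706), with Id4 at 0.19 and Skil at 0.18. Of 22 calcium and calcineurin/NFAT genes 16 lay above 0 (adjusted p = 0.260), with Camk2d at 0.15 and Rcan2, not detected on 9 of 16 arrays, at 0.21. Of 9 polycystin and Bicc1 partners 6 lay below 0 (adjusted p = 0.706), with Anks3 at -0.16 and Tsc1 at -0.14. Of 28 actin, smooth muscle and YAP/SRF targets 15 lay below 0 (adjusted p = 0.744), with Tagln at 0.18 and Lats2, not detected on 12 of 16 arrays, at -0.23. Values of genes not detected on many arrays lie near the background, and so do their fold changes.

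Stress and metabolic lists gave adjusted p of 0.138 or more in the mean comparison. Of 28 endoplasmic reticulum stress and ATF4 targets 18 lay below 0 (0.138), with Nupr1 at -0.32 and Ddit4 at -0.26. Of 19 inflammatory cytokines and NF-kB targets 13 lay below 0 (0.150), with the chemokine genes Cxcl1 at -0.32 and Cxcl5 at -0.23. Of 26 interferon response genes 17 lay below 0 (0.621), with Irgm1 at -0.34 and Isg15 at -0.33. Of 25 hypoxia and glycolysis genes 17 lay above 0 (0.354), with Adm at 0.21 and Egln1 at 0.17. Of 23 cholesterol synthesis genes 12 lay below 0 (0.986), with Msmo1 at 0.18 and Fasn at -0.16, and the median was negative where the mean was positive.

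Markers of other cell types did not pass in the mean comparison. Of 21 macrophage markers 14 lay above 0 (adjusted p = 0.621), with Mrc1 at 0.26 and Ccl4 at -0.25. Of 6 adipocyte markers 5 lay above 0 (0.609), with Cebpa at 0.20 and Gpd1 at -0.17, not detected on 7 and 9 of 16 arrays. Of 7 endothelial markers 5 lay below 0 (0.734), with Ramp2 and Esam both at -0.22. Of 11 skeletal muscle markers 9 lay below 0 (0.760), with the myosin light chain gene Myl1, not detected on 5 of 16 arrays, at -0.39. Skeletal actin Acta1 lay at 0.38 and passed when adjusted over the list alone (0.00333). Over all 20 lists 0 members passed over all genes in the mean comparison and 6 passed when adjusted over the list alone, these being Nkd2, Nrcam, Sox9, Col2a1, Mmp9 and Acta1.

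**Figure D4:**
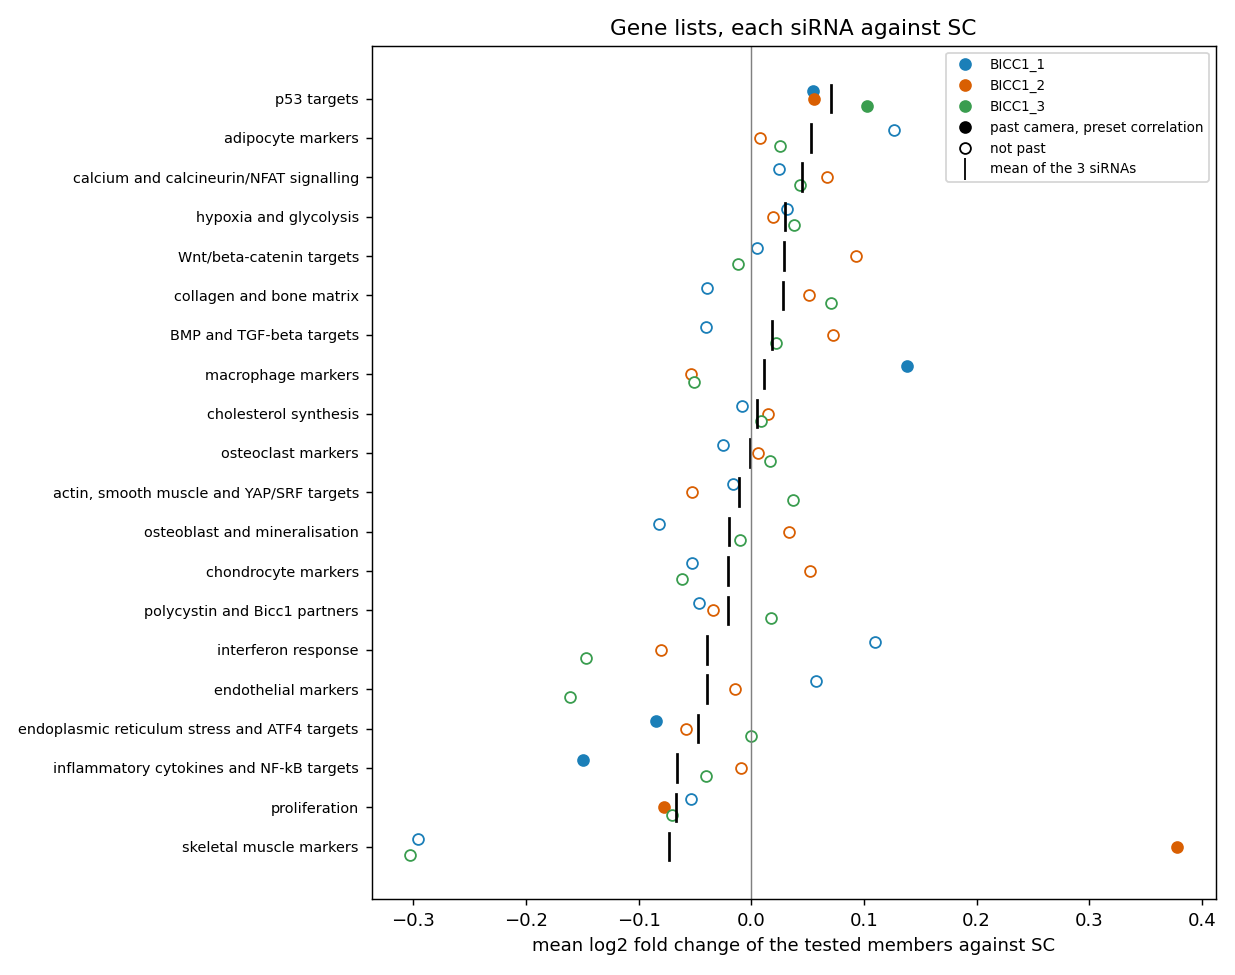
Mean log2 fold change of the tested members of 20 gene lists for each siRNA against SC (circles, filled where camera's preset-correlation test passed) and for the mean of the 3 siRNAs (bars). Targets of p53 lie above 0 for each siRNA, and skeletal muscle markers lie at 0.38 with BICC1_2 and at -0.30 with BICC1_1 and in the arrays labelled BICC1_3.

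Lists were also tested for each siRNA against the same SC arrays. With BICC1_1, 4 of 20 lists passed camera's preset test. Endoplasmic reticulum stress and ATF4 targets lay lower (21 of 28 below 0, mean -0.08, adjusted p = 0.00961, and adjusted p = 0.382 with an estimated correlation), with the stress gene Ddit4 at -0.39 and Sel1l, which acts in protein disposal from the reticulum, at -0.35, both past the test when adjusted over the list alone (0.0130 and 0.0133). Inflammatory genes lay lower (13 of 19 below 0, mean -0.15, adjusted p = 0.0275, and adjusted p = 0.406 with an estimated correlation), with the neutrophil chemokine genes Cxcl1 at -0.96 and Cxcl5 at -1.04, both past the test when adjusted over the list alone (0.00508 and 0.0152). Macrophage markers lay higher (18 of 21 above 0, mean 0.14, adjusted p = 0.00917), as did p53 targets (19 of 22 above 0, mean 0.05, adjusted p = 0.0447). The last pair both had adjusted p = 0.534 with an estimated correlation. Leaving out 1 array ended the macrophage call (SC replicate 2, BICC1_1 replicate 3 or 4, adjusted p 0.0525 to 0.0631), the stress call (SC replicate 2 or BICC1_1 replicate 2, 0.0603 and 0.0808), the inflammatory call (SC replicate 1 or 4, BICC1_1 replicate 1 or 2, 0.0579 to 0.0808) and the p53 call (SC or BICC1_1 replicate 1 or 4, SC replicate 3, BICC1_1 replicate 3, 0.0519 to 0.250). The inflammatory call also ended with no detection filter (0.0635), and the p53 call with median scaling (0.0609) and array quality weights (0.129). The stress mean was -0.05 with median scaling and the inflammatory mean -0.08 with the authors' table, both past the test.

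With BICC1_2, proliferation genes lay lower (25 of 31 below 0, mean -0.08, adjusted p = 0.00388), and skeletal muscle markers lay higher (10 of 11 above 0, mean 0.38, adjusted p = 0.00423). With an estimated correlation these gave adjusted p = 0.307 and 0.381. Myl1 lay at 1.33 with BICC1_2, -1.37 with BICC1_1 and -1.15 in the arrays labelled BICC1_3, and none of these passed the test. It varied as widely within groups, with log2 intensities of 5.09 to 9.18 on the SC arrays (SD 1.78), 4.74 to 8.25 with BICC1_1 (SD 1.53), 7.83 to 9.58 with BICC1_2 (SD 0.81) and 4.76 to 8.85 in the arrays labelled BICC1_3 (SD 2.03). The lower ends lie at the background, so these fold changes are not exact. Targets of p53 lay higher (18 of 22 above 0, mean 0.06, adjusted p = 0.0467), although the p53 target Rrm2b lay at -0.37 and passed when adjusted over the list alone (0.00265). The p53 list had adjusted p = 0.485 with an estimated correlation. Anks3, a binding partner of Bicc1, lay at -0.32 and the chemokine gene Cxcl12 at -0.41, both past the test when adjusted over the list alone (0.00301 and 0.0102). The muscle call ended without BICC1_2 replicate 2 (adjusted p = 0.0771) and with no detection filter (0.0981), and the proliferation call without BICC1_2 replicate 4 (0.0796). The p53 call ended with median scaling (0.0587) and without SC replicate 1, 3 or 4, BICC1_1 replicate 1, 2 or 4, or BICC1_2 replicate 3 (0.0505 to 0.190). The proliferation mean was -0.02 with median scaling, and the muscle mean 0.16 with the authors' table and 0.23 without SC replicate 4, all past the test.

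In the arrays labelled BICC1_3, p53 targets lay higher (20 of 22 above 0, mean 0.10, adjusted p = 0.000894), and the adjusted p was 0.744 with an estimated correlation. Pmaip1 (0.47), Trp53inp1 (0.36) and Ei24 (0.29) passed when adjusted over the list alone, as did Tnfrsf10b in the other direction (-0.67, on the brightest of 4 kept probes). The lysyl oxidase gene Loxl4 lay at 0.60 and the endothelial gene Esam at -0.56, each past the test when adjusted over its list alone (0.0104 and 0.0119). The p53 mean was 0.06 without the 3 arrays that stood apart (adjusted p = 0.00405), without replicate 1 of the group alone (0.00992) and with array quality weights (0.00714). Over all lists, 0 members passed over all genes in any of the 3 comparisons with SC, while 9, 6 and 9 passed when adjusted over the list alone with BICC1_1, BICC1_2 and in the arrays labelled BICC1_3. The p53 calls with BICC1_1 and BICC1_2 ended without the 3 arrays that stood apart (means 0.03 and 0.04, adjusted p = 0.226 and 0.117).

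Direct comparison of the siRNAs tested which genes differed between them. Bicc1 stood at 53.7%, 33.3% and 93.3% of control with BICC1_1, BICC1_2 and in the arrays labelled BICC1_3. A difference can therefore follow the siRNA or the level of Bicc1, which the comparison cannot tell apart. Ergic1 was 1.15 log2 higher with BICC1_1 than with BICC1_2 (SE 0.07, adjusted p = 5.32e-07), and 1.19 log2 lower with BICC1_2 than in the arrays labelled BICC1_3 (log2 -1.19, adjusted p = 2.91e-07). Atg5 gave 0.64 and -0.66 in the same comparisons (adjusted p = 0.00350 and 0.00164). Bicc1 itself was higher with BICC1_1 than with BICC1_2 by 0.69 (adjusted p = 0.0430), and lower than in the arrays labelled BICC1_3 by -0.80 with BICC1_1 (0.0276) and -1.49 with BICC1_2 (2.03e-05). Cxcl1 (-1.12, adjusted p = 0.0366), the transmembrane collagen gene Col23a1 (-0.77, 0.00812) and Mrgprf (-0.70, 0.00810) were lower with BICC1_1 than with BICC1_2. Mrgprf (-0.62, adjusted p = 0.0276) and the carboxypeptidase-like gene Cpxm1 (-0.60, 0.0454) were lower, and Sdcbp2 higher (0.54, 0.0458), with BICC1_1 than in the arrays labelled BICC1_3. Bmp4 (0.73, adjusted p = 0.0174) and Sostdc1 (0.57, 0.0244) were higher with BICC1_2 than in the arrays labelled BICC1_3. Mrgprf was thus lowest at the middle level of Bicc1, which argues against a steady course with Bicc1 for this gene. Against SC, with BICC1_1, BICC1_2 and the arrays labelled BICC1_3, Cxcl1 lay at -0.96, 0.16 and -0.16. Bmp4 lay at -0.09, 0.19 and -0.54. Neither kept the order of Bicc1, but none of these values passed the test against SC.

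Under the alternatives, Ergic1 passed in all 27 for both comparisons, as did Bicc1 between BICC1_2 and the arrays labelled BICC1_3. Between BICC1_1 and BICC1_2, Atg5 and Mrgprf missed the threshold with median scaling (adjusted p = 0.0689 for each, over ranges of 2.74e-05 to 0.0689 and 0.00369 to 0.0689), and Col23a1 did so without BICC1_2 replicate 2 (0.0553, over 0.00137 to 0.0553). Cxcl1 missed it in 15 of 27 (0.0150 to 0.150), among them leaving out SC replicate 1 or 2, BICC1_1 replicate 1, 2 or 3, any array of BICC1_2, or the 3 arrays that stood apart (0.0629), and the fit with the replicate number as a block (0.0676). Bicc1 missed it in 16 of 27 (0.0150 to 0.201), among them leaving out SC replicate 1, 2 or 3, BICC1_1 replicate 1, 2 or 3, BICC1_2 replicate 1, 2 or 4, or replicate 2, 3 or 4 of the arrays labelled BICC1_3. Between BICC1_1 and those arrays, Bicc1 missed it in 11 of 27 (0.0157 to 0.347), among them leaving out SC replicate 3, BICC1_1 replicate 1, 2 or 4, BICC1_2 replicate 2 or any array of the group, and Mrgprf in 9 of 27 (0.0190 to 0.347), among them leaving out BICC1_1 replicate 1 or 2, BICC1_2 replicate 2, or replicate 2, 3 or 4 of the group. Cpxm1 missed it in 21 of 26 (0.0291 to 0.538), and of the 16 arrays left out in turn it stayed past the test without BICC1_1 replicate 3, BICC1_2 replicate 1 or 4, or replicate 4 of the group. Without the 3 arrays that stood apart its adjusted p was 0.0814. Sdcbp2 missed it in 22 of 27 (0.0279 to 0.532), and of the 16 arrays it stayed past the test without SC replicate 2 or BICC1_2 replicate 4. Without the 3 arrays its adjusted p was 0.127. Between BICC1_2 and the arrays labelled BICC1_3, Bmp4 missed it in 8 of 27 (0.000218 to 0.421), among them leaving out BICC1_2 replicate 1, 2 or 3, replicate 3 or 4 of the group, or the 3 arrays (0.0646). Sostdc1 did so in 9 of 27 (0.00999 to 0.367), among them leaving out BICC1_2 replicate 1, 2 or 3, replicate 1 or 4 of the group, or the 3 arrays (0.0574), and Atg5 with median scaling (0.157) and separate fits (0.163, over 1.74e-05 to 0.163). With the authors' table the differences were smaller, Cxcl1 -0.60, Col23a1 -0.18 and Mrgprf -0.33 between BICC1_1 and BICC1_2, Cpxm1 -0.14, Sdcbp2 0.25 and Mrgprf -0.29 between BICC1_1 and the arrays labelled BICC1_3, and Sostdc1 0.20 between BICC1_2 and those arrays. With no background correction Col23a1 lay at -0.42, Cpxm1 at -0.32 and Sostdc1 at 0.38.

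In all, 27 genes differed between BICC1_1 and BICC1_2 (14 higher and 13 lower with BICC1_1), 7 between BICC1_1 and the arrays labelled BICC1_3 (1 higher, 6 lower), and 11 between BICC1_2 and those arrays (2 higher, 9 lower). Without 1 array the first count was 3 to 16 on leaving out SC replicate 1, 2 or 3 or any array of BICC1_1 or BICC1_2, and 43 without replicate 1 of the arrays labelled BICC1_3. The second was 1 to 4 without SC replicate 3, BICC1_1 replicate 1, 2 or 4, BICC1_2 replicate 2 or 3, or replicate 2, 3 or 4 of the arrays labelled BICC1_3, and the third was 5 to 7 without BICC1_1 replicate 1 or 4, any array of BICC1_2, or replicate 1, 3 or 4 of the arrays labelled BICC1_3, and 19 without replicate 2 of these. The counts were 2, 0 and 2 with median scaling and 5, 0 and 2 with separate fits. The count between BICC1_1 and BICC1_2 was 6 with the replicate number as a block (3 higher, 3 lower) and 71 with array quality weights (35 higher, 36 lower), and that between BICC1_2 and the arrays labelled BICC1_3 was 7 without the 3 arrays that stood apart (0 higher, 7 lower). By limma at an unadjusted p under 0.05 the counts were 610, 582 and 792.

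Muscle, bone and immune lists differed between the siRNAs by camera's preset test. Skeletal muscle markers were higher with BICC1_2 than with BICC1_1 (9 of 11 in that direction) and than in the arrays labelled BICC1_3 (11 of 11). Their adjusted p was 0.182 and 0.345 with an estimated correlation. BMP and TGF-beta targets were lower with BICC1_1 than with BICC1_2 (12 of 16 below 0, mean -0.11, camera adjusted p = 0.00772, fry 0.0184). Their adjusted p was 0.0901 with an estimated correlation, and the call ended without the 3 arrays that stood apart (-0.08, adjusted p = 0.0760). Osteoblast and mineralisation genes (14 of 18 below 0, adjusted p = 0.0119) and collagen and bone matrix genes (19 of 30, 0.0147) lay lower with BICC1_1 than with BICC1_2. With an estimated correlation these gave adjusted p = 0.182 and 0.579. Leaving out BICC1_1 replicate 2 (0.0534 and 0.262) or BICC1_2 replicate 4 (0.115 and 0.138) ended both bone calls, and leaving out BICC1_1 replicate 4 (0.0737) or BICC1_2 replicate 3 (0.0747) ended the collagen call. A stricter detection filter ended the osteoblast call (0.0666). Macrophage markers lay higher with BICC1_1 than with BICC1_2 (19 of 21 above 0, mean 0.19, adjusted p = 0.000125), with adjusted p = 0.379 with an estimated correlation. With the authors' table the muscle means were -0.23 (BICC1_1 minus BICC1_2) and 0.26 (BICC1_2 minus the arrays labelled BICC1_3) in place of -0.67 and 0.68, the osteoblast mean -0.06 and the BMP mean -0.07. The muscle means were -0.43 and 0.43 with no detection filter, and the first was -0.43 with no background correction, and the collagen mean went from -0.09 to -0.14 without BICC1_1 replicate 3.

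Several of these list differences moved with the arrays whose ribosomal and NADH dehydrogenase genes stood apart. Interferon response genes were higher with BICC1_1 than with BICC1_2 (22 of 26 above 0, mean 0.19, adjusted p = 0.0147) and than in the arrays labelled BICC1_3 (22 of 26, mean 0.26, adjusted p = 0.00135). With an estimated correlation these gave adjusted p = 0.579 and 0.424. Macrophage markers were higher with BICC1_1 than in the arrays labelled BICC1_3 (18 of 21, mean 0.19, adjusted p = 0.00323), with adjusted p = 0.424 with an estimated correlation. Without the 3 arrays the interferon means turned to -0.02 and -0.03 and the macrophage mean to -0.01. Without BICC1_1 replicate 3 alone the interferon means were -0.03 (adjusted p = 0.623) and 0.04 (0.449) and the macrophage call ended (0.205). Without replicate 1 of the arrays labelled BICC1_3 the interferon (0.0819) and macrophage (0.669) calls against that group ended, and without BICC1_2 replicate 4 the interferon call between BICC1_1 and BICC1_2 did (0.0757). That interferon mean was 0.30 without BICC1_1 replicate 2. With array quality weights the interferon (0.529 and 0.686) and macrophage (0.915) calls ended, and the first interferon call also with a stricter detection filter (0.223). Collagen and bone matrix genes (20 of 30 below 0), BMP and TGF-beta targets (13 of 16 below 0), stress and ATF4 targets (21 of 28 below 0) and endothelial markers (6 of 7 above 0) also passed between BICC1_1 and the arrays labelled BICC1_3 (adjusted p = 0.00157, 0.0449, 0.00504 and 0.00504). With an estimated correlation these gave adjusted p = 0.424, 0.257, 0.265 and 0.257. All of them ended without replicate 1 of that group (0.550, 0.0536, 0.129 and 0.106), without the 3 arrays (0.0520, 0.0520, 0.0620 and 0.0520) and with array quality weights (0.0521, 0.0521, 0.0668 and 0.0521), and the BMP call also without BICC1_1 replicate 1 or 3 or replicate 2, 3 or 4 of that group (0.0588 to 0.204). The stress call also ended with median scaling (mean -0.02 in place of -0.08, adjusted p = 0.159), and with it the collagen and BMP means were -0.04 and -0.03, still past the test. The collagen mean was -0.07 without BICC1_1 replicate 2 and -0.18 with every probe tested, in place of -0.11, and the endothelial mean 0.11 with no detection filter in place of 0.22. Actin, smooth muscle and YAP/SRF targets lay lower with BICC1_2 than in that group (20 of 28 below 0, adjusted p = 0.0117). Their adjusted p was 0.658 with an estimated correlation, and 0.368 without replicate 1 of that group or 0.541 without the 3 arrays. With median scaling their mean was -0.01 in place of -0.09 (0.301), and the call also ended with array quality weights (0.328) and a stricter detection filter (0.128). With the authors' table the interferon means were 0.09 and 0.12, the macrophage mean 0.09, the endothelial mean 0.09 and the BMP mean -0.04, still past the test.

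Fold changes of the siRNAs were also compared across all 9560 genes, which are not independent replicates. They correlated at 0.428 between BICC1_1 and BICC1_2 (Spearman 0.465), at 0.617 between BICC1_1 and the arrays labelled BICC1_3 (0.599), and at 0.391 between BICC1_2 and those arrays (0.424). Unchanged groups simulated with shared controls, and with noise independent between genes, correlated at 0.250, 0.249 and 0.246. With the SC arrays split, so that no control was shared, the means were 0.159, 0.389 and 0.174. The covariances were 0.00700, 0.0144 and 0.00812 against simulated 0.00386, 0.00382 and 0.00380, differences of 0.00314, 0.0106 and 0.00432. The pair with the highest correlation was the 1 whose groups each hold an array that stood apart most. The jackknife SEs of the correlations were 0.126, 0.275 and 0.170. Without the 3 arrays the correlations were 0.363, 0.472 and 0.414, against simulated 0.349 (0.304 to 0.409), 0.349 (0.266 to 0.418) and 0.351 (0.302 to 0.410). That of BICC1_1 and BICC1_2 lay inside the simulated range. That of BICC1_1 and the arrays labelled BICC1_3 lay above it, and that of BICC1_2 and those arrays just above it. The simulation leaves out variation that genes share on an array, so its ranges are too narrow to exclude unchanged groups. The covariance differences were then 0.00190, 0.00403 and 0.00257. Leaving out BICC1_1 replicate 3 alone brought the correlation of 0.617 to 0.294, and leaving out BICC1_2 replicate 3 brought 0.391 to 0.242.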

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

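The tests of explanations in this part were chosen after the results were seen, while the counts over other splits of the arrays were planned. An array was set apart when its gap to the nearest of the other 3 in its group took up most of the group's range. Chance sets an array apart in about 1 in 20 groups, or 15.4 of the 308 groups tested. In these data 28 were set apart, 22 of them on replicate 1 of the arrays labelled BICC1_3, BICC1_1 replicate 3 or BICC1_2 replicate 3.

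Replicate 1 of the arrays labelled BICC1_3 and BICC1_1 replicate 3 had first principal component scores of 41.81 and 21.6 (46.5% of the variance) and median correlations with the other arrays of 0.9756 and 0.9878. An effect of an siRNA is argued against, since the ribosomal protein median of the other 3 arrays labelled BICC1_3 lay only -0.0327 log2 from that of the SC arrays, and weaker hybridisation is argued against by 12863 probes detected on replicate 1. A loss of short transcripts in the RNA preparation or amplification may account for these 2 arrays, as other genes with a genomic span under 3 kb had a median of -0.361 on replicate 1 and -0.176 on BICC1_1 replicate 3, against -0.0493 to 0.0429 on the other 13. The BICC1_1 replicate 3 value lay inside the range of the others with median scaling (-0.102). For BICC1_2 replicate 3 the same median was -0.0261, inside that range, and 0.0505 with median scaling, which leaves the explanation open there.

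The arrays labelled BICC1_3 kept Bicc1 at 93.3% of control. This mean was raised by replicate 1, which lay 0.314 log2 above the median of the group's other arrays. Over the alternatives the log2 difference from SC went as low as -0.182. An exchange of labels with BICC1_1 or BICC1_2 is argued against, because 0 of the 8 arrays of those groups had Bicc1 at or above the lowest SC array or array labelled BICC1_3. An exchange with the SC arrays is argued against as the reason for the missing fall. Mean Bicc1 was 10.55 in SC and 10.45 in the arrays labelled BICC1_3, low in neither group. Since it differed between them by only -0.0994 log2, Bicc1 cannot tell whether their labels were exchanged. An siRNA that lowers the transcript little or not at all stays open, with a lower 95% limit of 77.1% of control. Protein was not analysed here, so an siRNA that acts on translation was not tested.

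Ergic1, Atg5 and Tnrc6c passed the test against SC with BICC1_2 and not with BICC1_1. A response in proportion to the loss of Bicc1 predicts -0.624, -0.329 and -0.303 with BICC1_1, where 0.0417 (SE 0.0746), 0.0595 (SE 0.0817) and -0.133 (SE 0.0778) were measured. These SEs leave out the error of the predictions, which rest on genes picked for passing with BICC1_2. The gaps of Ergic1 and Atg5 are large and argue against such a response for these genes. The gap of Tnrc6c is too small to decide. The 3 arrays that stood apart are argued against too, since without them Ergic1 lay at -1.11, Atg5 at -0.599 and Tnrc6c at -0.538 with BICC1_2, all past the test. A response that needs Bicc1 to fall below a threshold stays open. Silencing of other transcripts by the BICC1_2 sequence may also account for these genes, as 4 genes or unnamed probes other than Bicc1 were lower with this siRNA, but the siRNA sequences are not in the sources used here.

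For other named genes, the differences of single arrays from the median of the other 3 in log2 were as follows. On replicate 1 of the arrays labelled BICC1_3 they were Bicc1 0.314, Anks3 0.0906, Irgm1 -0.740, Adm -0.429, Lats2 0.835, Ccl4 -1.91 and Tnfrsf11a 0.389, and in list means collagen and bone matrix 0.310 (for a set of collagen genes the median was 0.114, and -0.0261 with median scaling), cholesterol synthesis 0.159, actin, smooth muscle and YAP/SRF targets 0.221 and macrophage markers -0.671. On BICC1_1 replicate 3 they were Cdh11 -0.444, Irgm1 -0.822 and hypoxia and glycolysis genes 0.122, and on BICC1_2 replicate 3 Thbs1 0.276, Irgm1 -0.727, Msmo1 0.291 and p53 targets 0.0516. On other arrays they were Tnfrsf10b 0.537 (replicate 3 of the arrays labelled BICC1_3), Isg15 1.13 (SC replicate 2) and 0.470 (BICC1_2 replicate 1), Cebpa -0.156 (BICC1_1 replicate 4), osteoblast and mineralisation genes -0.0596 (replicate 4 of the arrays labelled BICC1_3) and chondrocyte markers -0.0966 (replicate 2 of these).

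Effects of different siRNAs also differed by the test of the difference itself, with the adjusted p given above. BICC1_1 minus BICC1_2 gave Ergic1 1.145, Bicc1 0.689, Atg5 0.6407, Cxcl1 -1.121, Col23a1 -0.7747 and Mrgprf -0.7001. BICC1_1 minus the arrays labelled BICC1_3 gave Sdcbp2 0.5437, Bicc1 -0.7985, Mrgprf -0.6223 and Cpxm1 -0.6022. BICC1_2 minus those arrays gave Bmp4 0.7275, Sostdc1 0.5694, Bicc1 -1.487, Ergic1 -1.192 and Atg5 -0.6586.

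Other splits of the same arrays tested whether the counts could arise from arbitrary groups. Of the 35 splits of the 8 arrays in each comparison, 1, the real one, gave as many genes with BICC1_1 (2 genes, highest other 0), BICC1_2 (5, highest other 0) and the arrays labelled BICC1_3 (1, highest other 0). The same held between BICC1_1 and BICC1_2 (27, highest other 1, with the splits that part all 4 same-numbered pairs included), BICC1_1 and the arrays labelled BICC1_3 (7, highest other 5), and BICC1_2 and those arrays (11, highest other 0), each 1 of 35. For the mean of the 3 siRNAs 2 of 100 splits gave as many genes (1, highest other 1), the real gene being the targeted Bicc1. The shares of these 7 counts lie under 0.05 without adjustment over the 7, and 1 of 35 is the lowest share possible. Where the highest other count was 0, 1 gene past the test is enough for that share. The targeted Bicc1 was such a gene with BICC1_1, with BICC1_2 and between BICC1_2 and the arrays labelled BICC1_3. In these comparisons the share therefore says nothing about the genes other than Bicc1. Between BICC1_1 and BICC1_2 most of the splits do not keep the pairing by number. Too few keep it to reach 0.05, so for that count chance is not excluded. For lists in the mean comparison 67 of 100 splits gave as many (2 lists, highest other 9), so chance is not excluded there. What set apart the split with 9 lists was not tested. For genes changed the same way by all 3 siRNAs (0, highest other 0) 100 of 100 splits gave as many, which a count of 0 fixes in advance, so the splits say nothing about it.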

How the results depend on the processing

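The alternatives that leave out 3 or 2 arrays were chosen after seeing the data, and all others were planned. Of 2319 values of named genes and lists under the alternatives, 2080 kept their direction and side of the threshold, 227 kept their direction but missed it, 1 newly passed it (Nkd2 in the mean comparison with array quality weights), 4 moved and 7 reversed. Many of the 2319 belong to genes not past the test in the main fit, such as Pkd1 and most named genes of the mean comparison. Such values had no call to lose, so the share of 2080 overstates how firm the calls are. The count of genes changed the same way by all 3 siRNAs was 0 in all 29 alternatives, where stricter thresholds could only keep a 0. Under every scaling the median of all genes lay within 0.0612 log2 of 0. With median scaling, though, the share of genes at an unadjusted p under 0.05 that were higher went from 52.8% to 74.4% with BICC1_1, from 59.5% to 83.7% with BICC1_2, from 53.9% to 63.4% in the arrays labelled BICC1_3 and from 57.2% to 80.6% in the mean comparison, and for the pairs below from 45.7%, 56.7% and 55.2% to 41.3%, 68.8% and 71.7%. The slide was not given in the labels, so a slide block was not run, and separate fits do not apply to the mean comparison or the lists. The cause was not tested for the values below, except that leaving out arrays leaves fewer to test and stricter thresholds call fewer genes by construction.

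Genes changed are given for BICC1_1, BICC1_2, the arrays labelled BICC1_3 and the mean against SC, then for BICC1_1 against BICC1_2 (first pair), BICC1_1 against the arrays labelled BICC1_3 (second) and BICC1_2 against these (last). With median scaling the counts were BICC1_1 0, BICC1_2 2, BICC1_3 0 and pairs 2, 0 and 2 (0 higher, 2 lower), and Bicc1 with BICC1_1 lay at -0.85 (adjusted p = 0.224). The authors' table gave BICC1_3 2 and the last pair 17, and its calls split higher to lower as 1 to 2 for BICC1_1, 1 to 6 for BICC1_2 and 5 to 5 for the second pair; no background correction gave 1 to 2 for BICC1_1. Testing every probe gave BICC1_1 1 and the first pair 17. Separate fits gave BICC1_1 0, BICC1_3 0, pairs 5, 0 and 2, and Bicc1 with BICC1_1 at -0.898 (adjusted p = 0.145). Array quality weights, which gave the 3 arrays that stood apart 0.105, 0.233 and 0.578, gave BICC1_1 30, BICC1_2 60, BICC1_3 14, the mean 26 and the first pair 71. A log2 fold change of at least 1 left BICC1_1 0, BICC1_2 2, BICC1_3 0, the mean 0 and pairs 2, 0 and 2, and an adjusted p under 0.01 left BICC1_1 0, BICC1_3 0 and pairs 4, 1 and 4. In the mean comparison the lists past the test were 0 with an estimated correlation and 0 by fry, and fry called 1 list in the first pair.

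With the replicate number as a block the counts were BICC1_1 1, BICC1_3 4 and pairs 6, 2 and 6, where the first pair has numbers that pair its arrays. In that pair the block ended the call of Cxcl1 and of no other named gene or list. In the other comparisons a pairing by number was not shown. Over all groups 9 of 24 same-numbered correlations were over 0.1, and their median was -0.025 against 0.024 for other numbers. Of 16 arrays, 6 correlated best with their own number. The arrays that stood apart weigh on these correlations, with 0.705 between BICC1_1 replicate 3 and replicate 1 of the arrays labelled BICC1_3. A pairing by number is therefore not excluded either.

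Without 3 arrays the counts were BICC1_2 11, BICC1_3 0 and the last pair 7. The interferon means reversed to -0.0178 (BICC1_1 minus BICC1_2) and -0.0317 (BICC1_1 minus the arrays labelled BICC1_3), and the macrophage mean to -0.0118 (the latter pair). Without 2 arrays the counts were BICC1_1 9, BICC1_2 23, the first pair 66 and lists 4, with interferon -0.0293 and -0.0317 and macrophage -0.0118. Leaving out 1 array gave counts of 0 to 5, 2 to 9, 0 to 12 and 0 to 1 against SC and 3 to 43, 1 to 8 and 5 to 19 for the pairs, and 1 to 4 lists. It gave Bicc1 with BICC1_1 at -0.97 to -0.82, interferon (BICC1_1 minus BICC1_2) at -0.0293 to 0.295, the lowest without BICC1_1 replicate 3, and correlations of 0.299 to 0.483 (first pair) and 0.294 to 0.673 (second pair).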

Other observations

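The proportional-response test of the unnamed probe below was chosen after its values were seen, and so were the genes named in this part.

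With arrays weighted by their quality 60 genes passed the test with BICC1_2. The genes named here were picked by eye from these and were not tested as a group, and the chondrocyte and collagen lists did not pass with BICC1_2 (camera adjusted p = 0.608 and 0.310). The collagenase gene Mmp13 rose by 1.24 log2 (adjusted p = 0.0109), against 1.28 and adjusted p = 0.128 without weights. The matrix genes Matn4 (0.62), Col23a1 (0.66) and Col18a1 (0.40) and the BMP-family gene Gdf10 (0.54) were also higher, as were ceruloplasmin Cp (0.52) and the iron exporter gene Slc40a1 (0.51). The membrane metalloproteinase genes Mmp14 (-0.31) and Mmp17 (-0.55), the heme-degrading enzyme gene Hmox1 (-0.28) and Anks3 (-0.32) were lower. Without weights none of these passed, with adjusted p from 0.0665 (Col23a1 and Mmp17) to 0.910 (Mmp14), and none was among the 11 called with BICC1_2 without the 3 arrays that stood apart. In the mean of the 3 siRNAs the collagen receptor gene Mrc2 (0.47), Slc40a1 (0.41) and the cell-cycle inhibitor gene Cdkn1c (0.31) passed with weights, and Nkd2 (-0.32) was lower, with adjusted p of 0.173 to 0.407 without weights. The weighted test called 5 of the 5 genes and probes called without weights for BICC1_2.

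Between BICC1_1 and BICC1_2, genes outside the naming rule included Atg12, whose product is joined to that of Atg5 in autophagy, which was higher with BICC1_1 (0.47 log2, adjusted p = 0.0366). Tnrc6c (0.40) and Hmox1 (0.40) were also higher, and the matrix genes Matn4 (-0.65) and Prelp (-0.48), the BMP-family gene Gdf10 (-0.54) and the chemokine gene Ppbp (-0.52) were lower with BICC1_1. Tgfb1 was lower with BICC1_2 than in the arrays labelled BICC1_3 (-0.42). Without the 3 arrays that stood apart Atg12 and Ppbp were still called, while Tnrc6c, Hmox1, Matn4, Gdf10, Prelp and Tgfb1 were not. With the replicate number as a block, Ergic1, Bicc1 and Atg5 took up all the calls higher with BICC1_1 than with BICC1_2. Atg12, Tnrc6c and Hmox1 therefore lost their calls there, and so did most of Matn4, Prelp, Gdf10 and Ppbp.

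An unnamed probe was lower with BICC1_2 (-0.505 log2, adjusted p = 0.0134). A response in proportion to the loss of Bicc1 predicts -0.286 with BICC1_1 and -0.0317 in the arrays labelled BICC1_3. There -0.401 (SE 0.0774, limma adjusted p = 0.110) and -0.0541 were measured, near the prediction. With array quality weights the probe lay at -0.439 with BICC1_1 and at -0.507 with BICC1_2. Both then passed limma's test (adjusted p = 0.0107 and 0.000634). Both siRNAs were compared with the same SC arrays, which alone can make a probe low with both. The values therefore do not tell whether this probe follows Bicc1. The probe was picked because it passed the test with BICC1_2, and the transcript it reads is not analysed here.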
